A study of Arabidopsis thaliana with 4 samples.

How the data were processed

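The series measured messenger RNA in the upper and lower flanks of gravistimulated inflorescence stems of Arabidopsis thaliana, ecotype Col. Per the labels' protocols, seeds on Murashige and Skoog plates were kept cold (4 °C) for 3 days, then grown for 10 days at 23 °C without a dark period, and plants were moved to soil. Plants with primary stems of 4 to 8 cm were laid horizontally in dim light from no fixed direction at 23 °C for 10 or 30 min. The uppermost 5 mm was removed, and the next 3 cm of stem was cut lengthwise by hand into an upper and a lower flank. RNA (500 ng) was amplified and labelled with Cy3 or Cy5, per the labels' protocols, and the 2 flanks of one time were hybridized together on a 2-colour Agilent array of 60-base probes.

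There were 4 arrays, 2 for each time. On replicate 1 of each time Cy5 carried the lower flank, and on replicate 2 the dyes were swapped. The labels call the 2 arrays of a time biological replicates, and the labelling protocol also says that each cRNA was labelled with both dyes in separate reactions. Whether the swapped array held RNA of other plants or the same RNA labelled again is therefore not settled, and the p-values may measure technical spread only. No unstimulated stem was part of the series. Each array lay on a slide of its own and all were read on 1 day, so a slide block could not be fitted and was not run.

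Per the file headers, images were quantified with Agilent Feature Extraction 8.1.1.1. The deposited intensity values used here were the mean pixel brightness of each spot and the median brightness of its local background, with nothing subtracted. The deposited processed intensity of each channel was background-subtracted with spatial detrending and dye-normalized with linear and LOWESS factors, per the file headers, and the deposited log10 ratio is that of processed Cy5 over Cy3. The authors' series table of the same arrays held log10 ratios of lower over upper flank, which differed from the log10 ratios of the processed signals by at most 0.005. Its scale and direction follow from that comparison, and its column medians were 0, -0.00128, 0 and -0.00264. Feature Extraction's deposited flags (other values of 0 or 1) marked spots well above background, saturated spots and outlier spots. The genome build behind the array's annotation is not given in the sources used here.

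From the mean signals, background was corrected with normexp (offset 50) in limma 3.58.1 under R 4.3.3, and the ratios were normalized by loess within each array. Control spots (1075 of 22575) carried no weight in loess and were left out afterwards, as were outlier spots (124, 120, 451 and 152 on the 4 arrays in order of time and replicate). Ratios were turned to log2 of lower over upper flank on every array. Of 21500 gene probes, 20269 named 1 locus, 168 named several and 1063 named none. Locus names were matched to a RefSeq gene table (assembly TAIR10.1) used for symbols and neighbours only, in which 20187 of the one-locus probes were found and 82 were not. A gene was represented by its brightest one-locus probe (49 loci had several), and was tested if that probe was well above background on both arrays of at least 1 of the 4 combinations of flank and time, which left 18286 genes, 17754 of them with values on all arrays.

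The flank ratios of all 4 arrays were fitted together with limma (lmFit and eBayes), with a mean per time and no dye or replicate term, so that both times shared an estimate of the spread. From this fit came the flank difference at 10 min, at 30 min, their mean and their difference. For the level at 30 against 10 min, the average log2 signal of both channels was scaled between arrays (Aquantile) and compared between the 2 arrays of each time. P-values were adjusted by Benjamini-Hochberg over all genes tested, a gene was called at an adjusted p under 0.05, and every adjusted p below is limma's unless another test is named. The ± values are standard errors from the limma fit of each comparison. The flank fit has no dye term, so its spread holds each gene's dye effect. That effect cancels in the mean of the 2 arrays of a time. Over genes, the dye contrast had an SD of 0.121, against 0.0322 for the contrast that is neither flank, time nor dye. Flank errors and p-values of that fit thus measure dye effects more than spread between plants. Counts of genes at least 1.5-fold apart on both arrays of a time were taken without a test, beside the number of genes as far apart by dye.

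The 20 gene lists covered Aux/IAA, SAUR, GH3 and other early auxin-induced genes, auxin transport and perception, gravity sensing, gibberellin, brassinosteroid, ethylene, cytokinin response, jasmonate and wounding, touch and rapid stress, expansins and xyloglucan enzymes, heat shock, circadian and light, dark and sugar starvation, photosynthetic tissue, epidermis, xylem and fibre secondary wall, phloem and cambium, and flower. They held 314 distinct genes, of which 285 were tested. Lists were tested with limma's camera (preset correlation 0.01), with camera using an estimated correlation and with fry, each adjusted over the lists. With an estimated correlation camera has only the few degrees of freedom left by 4 arrays, and fry with the replicate block has fewer still. At 30 min SAUR and epidermis, with estimated correlations of 0.0545 and -0.107, both had an adjusted p of 0.241 in that camera test. Such ties come from the adjustment over the lists, which can give several lists the same value, so a tied value is not specific to a list. The epidermis call was lost although its estimated correlation was below 0. A call lost there is therefore not by itself evidence that the genes of a list are correlated. The groups, tests, lists and the alternatives to each processing step were fixed before the data were examined, unless said otherwise. So was the rule for named genes: the 15 called genes with the largest change in each direction and the same sign on every array, the 10 smallest p-values each way where fewer than 10 genes passed, members of a list that passed when adjusted over the list alone, and IAA1, IAA2, IAA5, IAA19, GH3.3, SAUR15 and PIN3. LAZY1, also on the rule's list, was not among the genes tested.

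The replicate number coincides with the dye orientation, so a fit with the replicate number as a block is the same as a fit with a dye term. Deviations of same-numbered arrays from their time means correlated over genes at 0.867, and 9661 genes differed by dye in the blocked fit. The number therefore pairs the arrays by dye. Blocked counts of genes called over all genes stand beside those counts where they differ by over 1.5 times, and blocked counts over a list alone are given for 10 and 30 min.

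Both fits were tested on simulated data made from the real genes' spreads (17754 genes, 50 seeded at each fold). For the flank ratios the noise was the spread left after the dye term, drawn independently for each array. Each gene kept the same dye effect at both times. No difference between plants or cut flanks shared by both arrays of a time was simulated. The flank rates therefore do not bear on whether the many small differences called with the dye term are responses to gravity. Without the dye term, 90% of genes seeded at 1.5-fold and 2% of those at 1.2-fold were recovered at 10 min, and 88% and 4% at 30 min; for the mean of both times 100% and 52%, and for the difference between times 48% and 0%. No unseeded gene was called in these flank comparisons. With the dye term every seeded gene was recovered, with between 26 and 39 unseeded genes called. For the level between times 96% were recovered at 1.5-fold and 10% at 1.2-fold, with 12 unseeded genes called. In simulated signals, a 2-fold rise of 200 spots came out as a median log2 of 0.89, so the offset shrinks differences of dim spots.

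Median Cy5 and Cy3 signals were 333 and 227 on replicate 1 and 184 and 156 on replicate 2 at 10 min, and 214 and 178 on replicate 1 and 299 and 272 on replicate 2 at 30 min, over median backgrounds of 50 to 64. Of the gene probes, between 86.0% and 90.9% were well above background in a channel. The number of arrays limits the precision of every value. Alternatives covered background correction, normalization, the filter on dim probes, the choice of probe, the variance model, the deposited processed signals and series table, the replicate block, each time fitted alone and each array left out; those added after seeing the data are named in the closing section.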

Results

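Transcript levels were compared between the lower and upper flanks of horizontally placed inflorescence stems after 10 and 30 min of gravistimulation, with 2 arrays of swapped dyes per time. Such stems bend upward, with more growth on the lower flank, and the plant hormone auxin accumulates there. The comparisons ask which transcripts differ between the flanks at each time, at both times together and by different amounts at the 2 times, and which levels differ between the times in both flanks. All ratios are given as log2 of lower over upper flank, so that positive values mean higher in the lower flank. On each array 21500 gene probes were read, and 18286 genes were tested. The average log2 signals of the 2 arrays of a time differed with an SD over bright genes of 0.117 at 10 min and 0.203 at 30 min, against 0.276 to 0.360 for arrays of different times. The flank ratios of the 2 arrays of a time correlated over genes at -0.060 at 10 min and 0.438 at 30 min. Between times, arrays of the same dye orientation correlated at 0.267 and 0.277, and those of opposite orientation at -0.427 and -0.377. Flank ratios of single genes were thus not reproduced over all genes at 10 min.

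After 30 min, the largest flank difference was that of an Aux/IAA gene. IAA5 (AT1G15580), a repressor protein of auxin signalling and itself induced by auxin, was higher in the lower flank by 2.28 ± 0.04 (n = 2 arrays, adjusted p = 4.7e-04). AT5G66580, a gene without a symbol, followed with 1.91 ± 0.05. The SAUR genes SAUR19, SAUR20, SAUR21, SAUR22, SAUR23 and SAUR24, small auxin up RNAs that promote cell expansion, lay between 1.56 and 1.68. On the other side, AT1G78170, of unknown function, was higher in the upper flank (-0.998 ± 0.04, adjusted p = 0.00143), as were AT1G79160 (-0.79), the BTB and TAZ domain gene BT2 (-0.74) and the nitrate reductase gene NIA1 (-0.54).

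limma called 96 genes at 30 min, 60 higher in the lower and 36 higher in the upper flank, and the 21 genes with a difference of at least 2-fold were all higher in the lower flank. With the replicate number, and so the dye, as a block 6259 genes were called (3240 higher in the lower and 3019 in the upper flank), which included all 96 and 40 at or above 1.5-fold, with a median size of 0.09. With each array's ratios centred on their median in place of loess no gene was called, although all 96 kept their direction; the share higher in the lower flank, 62.5% of calls, was 89.4% with a normexp offset of 16, 83.3% with the deposited processed signals and 82.0% with the series table. With 30 min fitted alone 613 genes were called (228 higher in the lower and 385 in the upper flank). Leaving out either 10 min array repeats that test of the 30 min values, so these settings are not separate checks. With either 30 min array left out, which leaves 1 array of that time, more calls also lay in the upper flank.

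**Figure D1:**
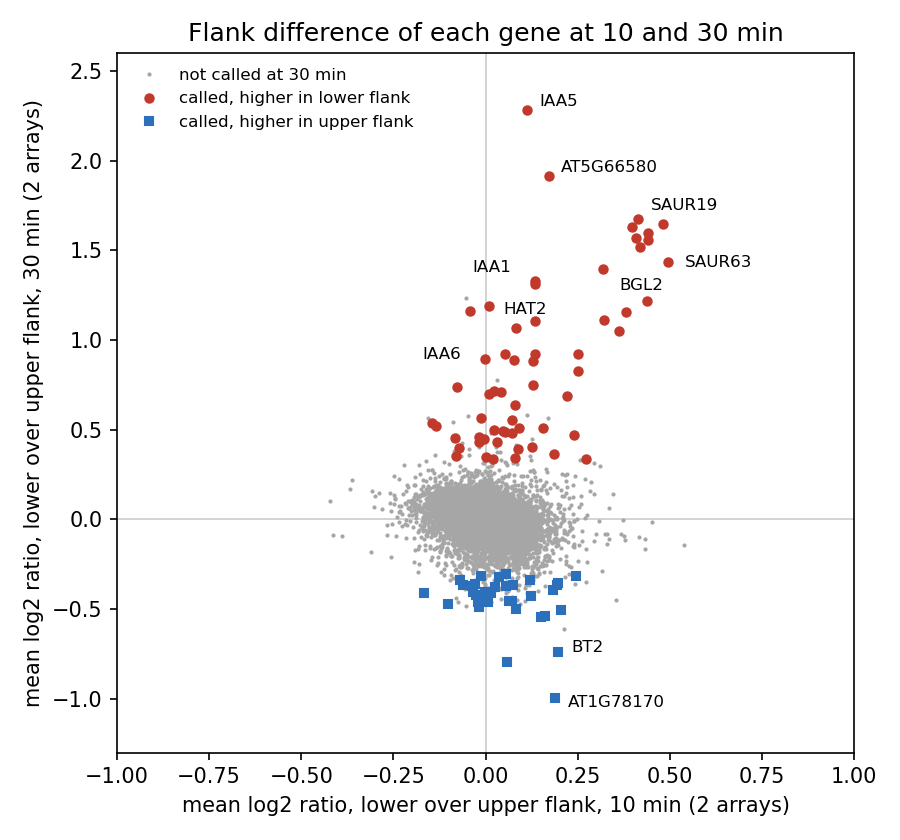
Mean log2 ratio of lower over upper flank (2 arrays per time) for each gene at 10 min (x axis) and 30 min (y axis); red circles and blue squares are the genes called at 30 min, 60 higher in the lower and 36 higher in the upper flank. IAA5 lies at 0.11 and 2.28, and SAUR19 at 0.41 and 1.68.

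Within the SAUR list, 15 of 26 measured members were called higher in the lower flank at 30 min. Adjusted over the list alone, 20 were higher, 1 was lower and 5 did not pass. Members of the chromosome 1 group included SAUR66 (1.52 ± 0.04), SAUR63 (1.43 ± 0.05), SAUR65 (1.22), SAUR64 (1.15) and SAUR68 (1.05). On chromosome 4 SAUR15 (1.11 ± 0.06) and SAUR14 (0.82 ± 0.05) were called. SAUR16 (0.58) and SAUR50 (0.55), on the same chromosome, were also above 0. SAUR32 was the member on the other side (-0.23, adjusted p = 0.310 over all genes). SAUR25 (AT4G13790), outside the list, was higher by 1.33 ± 0.04. The list median was 0.70, and camera called it up (adjusted p = 4.6e-28; adjusted p = 0.241 with an estimated correlation; fry adjusted p = 0.00577, and 0.0660 with the replicate block). Probes of near-identical SAUR genes can take up signal from each other's transcripts, so values of neighbours in a group are not independent.

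Of 24 measured Aux/IAA genes, encoding repressors of auxin signalling, 6 were called at 30 min, all higher in the lower flank. Besides IAA5 these were IAA1 (1.31 ± 0.07), IAA3 (1.06 ± 0.04), IAA2 (0.92 ± 0.07), IAA6 (0.89 ± 0.04) and IAA4 (0.64 ± 0.04). Adjusted over the list alone 11 passed, among them IAA19 (0.54, adjusted p = 0.0515 over all genes). The list median was 0.09 and its mean 0.34, and camera called it up (adjusted p = 4.2e-07; adjusted p = 0.241 with an estimated correlation; fry adjusted p = 0.0200, and 0.0726 with the block).

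Other early auxin-induced genes were divided. HAT2, a homeodomain leucine zipper transcription factor (1.19 ± 0.04), and PRE1, a small helix-loop-helix growth regulator (0.92 ± 0.05), were called, as was the ethylene synthesis gene ACS8 (0.43 ± 0.04), a dim gene well above background in the lower flank on 2 arrays and in the upper flank on 1. ACS4, an enzyme of ethylene synthesis, had 1.23 ± 0.15 and passed over its list alone (adjusted p = 0.0583 over all genes). GH3.3, an auxin-conjugating enzyme, had 0.07 ± 0.05 and did not pass. In this list of GH3 and other early auxin-induced genes, 3 of 15 members were called and 5 passed over the list alone, with a median of 0.02 (camera up, adjusted p = 0.00106; adjusted p = 0.241 with an estimated correlation; fry adjusted p = 0.0229, and 0.0977 with the block). AUF1, an F-box gene, and AT5G02760, a protein phosphatase 2C, had 1.11 and 1.16 and were called. BGL2, a glucanase of pathogen defence (1.39 ± 0.08), was also called.

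ARR7, a response regulator induced by cytokinin, was called (0.88 ± 0.04) and was the 1 member of 7 in the cytokinin response list to pass; the list median was 0.05. GA3OX1, which makes active gibberellin, was called (0.71 ± 0.05), and GA20OX1, an earlier step of that pathway, passed over its list alone (0.78 ± 0.11, adjusted p = 0.0871 over all genes), as did GA2OX2, which inactivates gibberellins (0.27). In the brassinosteroid list 3 of 7 members passed over the list alone, the synthesis genes CPD (0.26) and BR6OX2 (0.26) and the inactivating enzyme BAS1 (0.20), with a list median of 0.16. In the ethylene list (median 0.04, mean 0.21) 4 of 11 passed over the list alone: ACS4 and ACS8, which the list shares with the early auxin-induced genes and which have its largest values, the receptor gene ETR2 (0.26) and ACS6 (0.21). Camera called the brassinosteroid (adjusted p = 0.00250), ethylene (adjusted p = 6.0e-04) and cytokinin (adjusted p = 0.0386) lists up and did not call the gibberellin list (median -0.01, adjusted p = 0.306). With an estimated correlation the adjusted p was 0.241, 0.241, 0.264 and 0.417 in this order, and the cytokinin call was lost with the replicate block (adjusted p = 0.0879). With fry the brassinosteroid (adjusted p = 0.0709) and ethylene (0.0506) calls were lost, cytokinin response passed (0.0367), and gibberellin passed as well (0.0357). Under fry with the block only brassinosteroid of these 4 passed (adjusted p = 0.0412), while ethylene (0.156), cytokinin (0.116) and gibberellin (0.0881) did not.

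The named genes higher in the upper flank at 30 min had various functions. XTH24, a xyloglucan endotransglucosylase of the cell wall (-0.54 ± 0.06), the pectin methylesterase gene PME61 (-0.50 ± 0.05), the peroxidase gene PER64 (-0.46), CYP707A3, which breaks down abscisic acid (-0.49), BCAT4, of methionine-derived glucosinolate synthesis (-0.47), and BT4, related to BT2 (-0.45), were called. In the list of expansins and xyloglucan enzymes XTH24 was the 1 called member of 23; over the list alone 4 were lower and 1 higher, the expansin gene EXPA8 (0.15), and the median was -0.04 (camera down, adjusted p = 0.0179; adjusted p = 0.241 with an estimated correlation; fry adjusted p = 0.0506, and 0.0881 with the block).

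Markers of tissues were mostly higher in the upper flank at 30 min, by small amounts. The epidermis list had a median of -0.14, with the wax genes CER5 (-0.27 ± 0.03), KCS6 (-0.22) and MAH1 (-0.21) passing over the list alone. In photosynthetic tissue (median -0.14) LHCB5 (-0.19), LHCA4 (-0.18) and LHCA2 (-0.17), of the light-harvesting complexes, did so. In phloem and cambium (median -0.10) the phloem lectin gene PP2-A1 was called (-0.36 ± 0.04), and the sucrose transporter gene SUC2 (-0.17) and SEOR1 (-0.15), of sieve elements, passed over the list alone. Xylem and fibre genes had a median of -0.08 and no member passed. Camera called these 4 lists down (adjusted p = 2.4e-04, 4.9e-04, 5.8e-04 and 0.00177 in this order), and none held with an estimated correlation (adjusted p = 0.241 each). With fry photosynthetic tissue did not pass (adjusted p = 0.314), while epidermis, phloem and cambium, and xylem and fibre did (0.0281, 0.0350 and 0.0281); with the block only epidermis did (0.0412, 0.0881 and 0.0972). Over the 52 measured members of these lists, 33 were below 0 on both arrays and 1 was above.

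The other lists were not called by camera at 30 min, and of these fry called dark and sugar starvation (adjusted p = 0.0200, and 0.0412 with the block). Auxin transport and perception had a median of -0.02 over 23 genes (camera adjusted p = 0.916), with PIN3, an auxin efflux carrier of the endodermis, at 0.10 ± 0.04, and with the kinase genes PID (0.40) and WAG2 (0.22) and the auxin receptor gene AFB1 (0.16) passing over the list alone. Gravity sensing genes had a median of -0.04 over 10 genes (adjusted p = 0.157), jasmonate and wounding -0.03 (0.269), touch and rapid stress -0.01 (0.648), heat shock -0.00249 (0.569), circadian and light -0.06 (0.269), dark and sugar starvation -0.07 (0.0509), and flower 0.01 over 3 genes (0.916). The clock gene LHY was called (0.34 ± 0.04, adjusted p = 0.0446). Over their lists alone CCA1 (0.14) and PRR5 (-0.21), also of the clock, TCH4 (0.39), a xyloglucan enzyme induced by touch, and DIN10 (-0.22) and BCAT2 (-0.31), of the starvation list, passed.

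With the replicate block more members passed over their list alone at 30 min. In the SAUR list 20 were higher and 4 lower in the lower flank, in Aux/IAA 14 and 4, in GH3 and other early auxin-induced genes 6 and 1, in brassinosteroid 6 and 1, in ethylene 5 and 0, in cytokinin response 4 and 1, in gibberellin 5 and 2, and in auxin transport and perception 6 and 6. In epidermis 12 were lower, in xylem and fibre 11, in photosynthetic tissue 8 and in phloem and cambium 6, none of these lists having a higher member. Expansins and xyloglucan enzymes had 6 and 10, circadian and light 3 and 8, touch and rapid stress 6 and 5, jasmonate and wounding 3 and 5, gravity sensing 0 and 3, heat shock 2 and 0, dark and sugar starvation 1 and 2, and flower none.

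**Figure D2:**
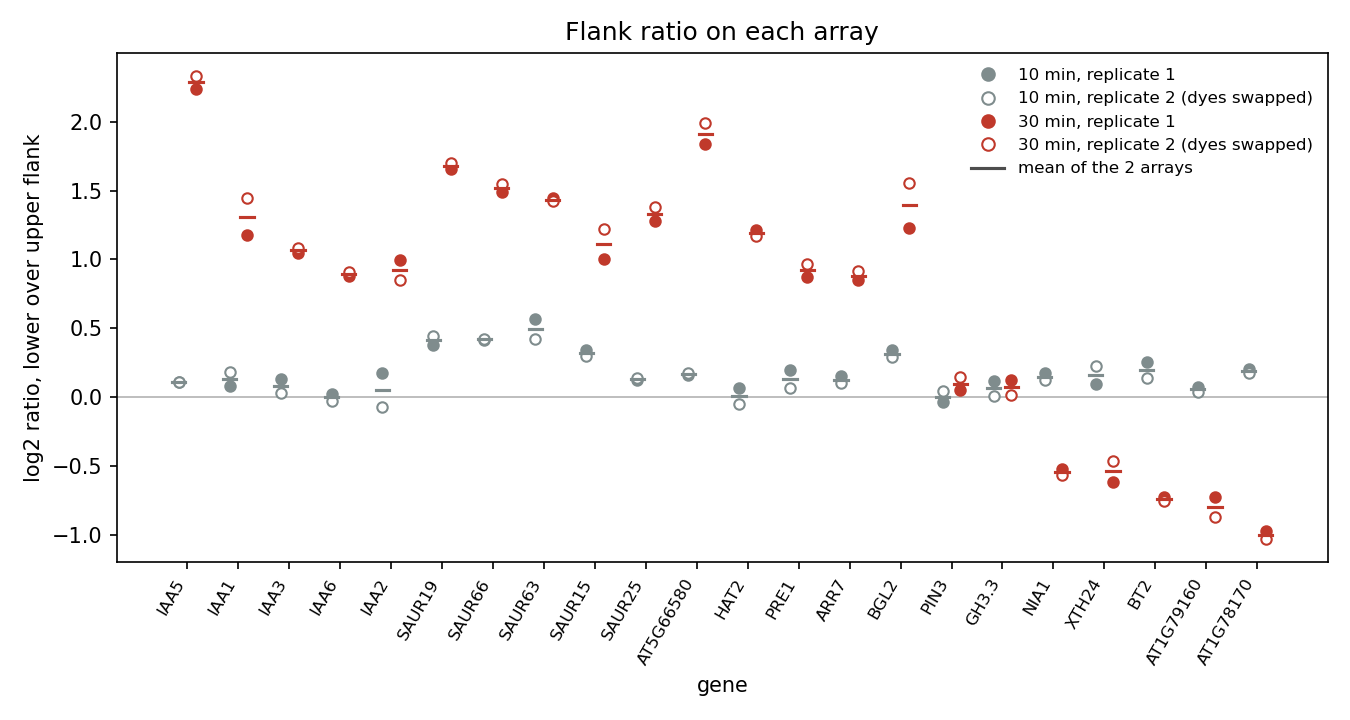
Log2 ratio of lower over upper flank on each of the 4 arrays for 22 genes; filled points are replicate 1, open points replicate 2 with swapped dyes, and bars the mean of the 2 arrays of a time. IAA5 has a mean of 2.28 at 30 min and 0.11 at 10 min, and AT1G78170 -0.998 and 0.19.

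After 10 min the largest flank differences were smaller, and SAUR genes were prominent among them. SAUR63 had 0.49 ± 0.05, SAUR24 0.48 ± 0.04 and SAUR19 0.41 ± 0.04, and of the 26 measured members 18 were above 0 on both arrays and none was below on both. IAA5 had 0.11 ± 0.04, IAA1 0.13 ± 0.07, IAA2 0.05 ± 0.07, IAA19 -0.09 ± 0.07 (from replicate 2 alone), GH3.3 0.06 ± 0.05 and PIN3 0.01 ± 0.04, none past the test. The unnamed gene AT1G64370 had the largest mean (0.54 ± 0.05), and CCA1, a transcription factor of the circadian clock, had 0.35 ± 0.03. Among the genes with the smallest p-values on the other side were PHB3, a prohibitin (-0.37 ± 0.06), AT3G62870, a ribosomal protein (-0.36 ± 0.04), and AKR2, an ankyrin repeat protein (-0.31 ± 0.03).

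No gene was called at 10 min by limma (smallest adjusted p = 0.367); 1115 genes had an unadjusted p under 0.05. With the replicate block 4224 genes were called, 2151 higher in the lower and 2073 in the upper flank, none of them at or above 1.5-fold, and with 10 min fitted alone 86 were called. Leaving out either 30 min array repeats that test of the 10 min values and is no separate check. Leaving out 10 min replicate 1 or 2, which leaves 1 array of that time, also gave calls.

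Adjusted over the SAUR list alone, 13 members passed at 10 min, all higher in the lower flank. They were SAUR14, SAUR15, SAUR19 to SAUR24, SAUR63 to SAUR66 and SAUR68, between 0.25 and 0.49. The list median was 0.21 (camera up, adjusted p = 1.0e-22; adjusted p = 0.359 with an estimated correlation; fry adjusted p = 0.0600). Camera also called up the lists of cytokinin response (median 0.07, adjusted p = 0.00549), phloem and cambium (0.07, 0.0124), and GH3 and other early auxin-induced genes (0.02, 0.0317), and called down touch and rapid stress (-0.03, 0.0317). With an estimated correlation the adjusted p of each of these was 0.544, and fry called none of the lists at 10 min. With the replicate block the last 2 calls were lost (adjusted p = 0.116 and 0.0571).

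Few single members of the other lists passed at 10 min over their list alone. GH3.6, an auxin-conjugating enzyme, had 0.21 ± 0.04, the expansin gene EXPA1 0.26 ± 0.04 and PP2-A1 0.19 ± 0.04. CCA1 and its partner LHY (0.27 ± 0.04) passed over the circadian and light list, whose median was -0.03 (camera adjusted p = 0.566). In the remaining lists no member passed without the block: Aux/IAA (median 0.00399), auxin transport and perception (-0.02), gravity sensing (0.00895), gibberellin (0.01), brassinosteroid (-0.04), ethylene (-0.02), jasmonate and wounding (-0.02), heat shock (-0.00956), dark and sugar starvation (-0.06), photosynthetic tissue (-0.02), epidermis (0.00364), xylem and fibre (0.01) and flower (0.04).

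With the replicate block members passed over their list alone at 10 min in every list except xylem and fibre. In the SAUR list 20 were higher in the lower flank, in GH3 and other early auxin-induced genes 5, in cytokinin response and in phloem and cambium 4 each, and in flower 1, with none lower. In Aux/IAA 6 were higher and 5 lower, in expansins and xyloglucan enzymes 7 and 4, in photosynthetic tissue 4 and 4, in circadian and light 3 and 6, in ethylene 2 and 2, in touch and rapid stress 2 and 9 and in gibberellin 1 and 3. In jasmonate and wounding 6 were lower, in auxin transport and perception 4, in epidermis and in dark and sugar starvation 2 each, and in brassinosteroid, gravity sensing and heat shock 1 each, with none higher.

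Without a test, no gene was at least 1.5-fold apart in the same direction on both arrays at 10 min, against 3 genes as far apart by dye (CRU2, RBCS1A and CRK20, named after their values were seen). At 30 min 36 genes were at least 1.5-fold higher in the lower flank on both arrays and 3 in the upper flank (AT1G78170, AT1G79160 and BT2), against 1 by dye (CRK20). At 2-fold the counts were 0 at 10 min and 20 at 30 min, all higher in the lower flank.

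**Figure D3:**
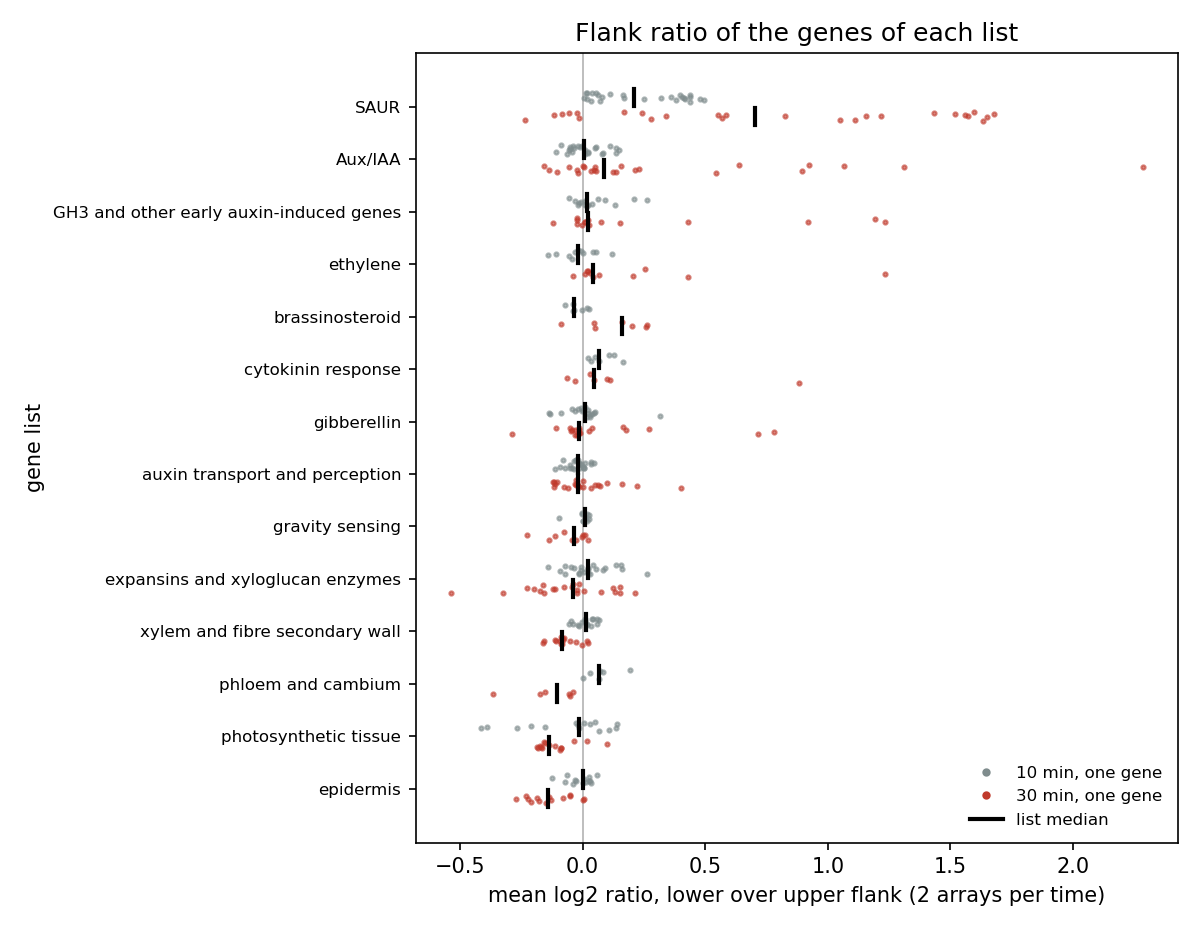
Mean log2 ratio of lower over upper flank of each measured gene of 14 lists (points) and the list median (black bars), at 10 min (grey) and 30 min (red), 2 arrays per time. The SAUR median is 0.21 at 10 min and 0.70 at 30 min, and the epidermis median is 0.00364 and -0.14.

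Over both times together, the mean flank difference put the same families first. IAA5 (1.198 ± 0.03), SAUR24 (1.06 ± 0.03), SAUR19 (1.05 ± 0.03) and AT5G66580 (1.04 ± 0.03) were higher in the lower flank on all 4 arrays (adjusted p = 0.00112 for the first 3 and 0.00156 for the last). BGL2 had 0.86 ± 0.06, ARR7 0.51 ± 0.03, and LHY, of the circadian clock, 0.30 ± 0.03. AT3G10020, of unknown function, was lower in the lower flank on all 4 arrays (-0.29 ± 0.02, adjusted p = 0.0384).

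For this mean limma called 40 genes, 37 higher in the lower and 3 in the upper flank, all of them also called at 30 min. The other 2 of the 3, AT1G78170 (-0.40) and AT1G79160 (-0.37), were above 0 at 10 min and are named here after their values were seen. With the replicate block 3629 were called (1813 higher in the lower and 1816 in the upper flank), with median centring in place of loess none, and with the arrays of each time averaged as 1 replicate, an alternative chosen after seeing the data, none (383 at an unadjusted p under 0.05). Leaving out 10 min replicate 1 or 2 gave 193 (117 and 76) or 212 (128 and 84) calls, and leaving out 30 min replicate 1 or 2 gave 158 (102 and 56) or 134 (94 and 40), so the nearly one-sided split did not hold in these fits.

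Camera called 11 lists for the mean of both times, led by SAUR (median 0.45, 13 of 26 called). Aux/IAA (0.05), GH3 and other early auxin-induced genes (0.07), cytokinin response (0.08), ethylene (0.03) and brassinosteroid (0.06) were also called up. Epidermis (-0.07), photosynthetic tissue (-0.06), dark and sugar starvation (-0.06), jasmonate and wounding (-0.02) and xylem and fibre (-0.03) were called down. None of the 11 held with an estimated correlation, and the smallest adjusted p was 0.191, for SAUR. With fry the calls of brassinosteroid (adjusted p = 0.224), ethylene (0.131), jasmonate and wounding (0.225), photosynthetic tissue (0.485) and xylem and fibre (0.0881) were lost, and gibberellin passed (0.0364). Fry with the block called brassinosteroid, jasmonate and wounding, dark and sugar starvation, and epidermis (adjusted p = 0.0495 each), and not SAUR (0.0569), Aux/IAA (0.0746), or GH3 and other early auxin-induced genes, cytokinin response and gibberellin (0.142 each).

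The flank difference was larger at 30 than at 10 min for IAA5, several SAUR genes and other auxin-induced genes. The difference of differences (30 min minus 10 min) was 2.17 ± 0.06 for IAA5 (adjusted p = 0.00339), 1.74 ± 0.07 for AT5G66580, 1.26 ± 0.05 for SAUR19, 1.18 ± 0.06 for HAT2 and 0.98 ± 0.06 for IAA3. On the other side it was -1.19 ± 0.05 for AT1G78170 (adjusted p = 0.0118), -0.94 ± 0.06 for BT2, -0.85 ± 0.07 for AT1G79160 and -0.69 ± 0.05 for NIA1. The last 4 genes were above 0 on both arrays at 10 min. IAA1 had 1.18 ± 0.10 and IAA2 0.87 ± 0.10, past the test over their list alone (adjusted p = 0.0576 and 0.0843 over all genes), while GH3.3 had 0.01 ± 0.07 and PIN3 0.09 ± 0.06.

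limma called 23 genes for this difference, 19 upward and 4 downward, all among those called at 30 min. With the replicate block 6879 were called (3425 upward and 3454 downward); only 2 were called with the deposited processed signals or the series table, and with median centring none, although all 23 kept their direction. Leaving out 10 min replicate 1 or 2 gave 291 (122 upward and 169 downward) or 430 (169 and 261) calls, and leaving out 30 min replicate 1 or 2 gave 287 (120 and 167) or 237 (104 and 133), so the larger side was then the downward one. Of the 60 genes higher in the lower flank at 30 min, 42 were above 0 on both 10 min arrays, and of the 36 higher in the upper flank 7 were below 0 and 21 above 0 on both. Over all genes the flank differences at 10 and 30 min correlated at -0.114, and genes are not independent replicates.

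The level averaged over both flanks differed between the times for many genes outside the auxin families. BT2 had a level lower by 2.98 at 30 than at 10 min (-2.98 ± 0.07, n = 2 arrays per time, adjusted p = 1.8e-04). ERD7, an early dehydration gene (-2.71 ± 0.09), GRP3S, a glycine-rich protein (-2.66 ± 0.09), DIN1, induced in darkness (-2.56 ± 0.08), and FSD1, an iron superoxide dismutase (-2.16 ± 0.07), were also lower. The cold and dehydration genes LTI30 (-1.97) and LTI78 (-1.93) were lower too. Higher at 30 min were AT5G37970, a methyltransferase (1.41 ± 0.07), NIMIN1, which binds the defence regulator NPR1 (1.32 ± 0.11), FAF2 (1.095 ± 0.09) and APS4, of sulfate assimilation (1.05 ± 0.11).

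In the dark and sugar starvation list 4 of 5 members were called lower at 30 min, among them DIN1 and DIN6, an asparagine synthetase (-1.79 ± 0.07), with a median of -1.06. In the circadian and light list 8 of 14 were lower, including LUX (-0.99 ± 0.07), PRR5 (-0.92), PRR7 (-0.83), PIF5 (-0.86), PIF4 (-0.83) and TOC1 (-0.53), and LHY was higher (0.40 ± 0.07). Among 26 SAUR genes (median -0.28) 11 were lower, such as SAUR63 (-0.69 ± 0.09) and SAUR68 (-0.64), and AT1G29490 was higher (0.50). Camera called these 3 lists down (adjusted p = 1.3e-06, 4.0e-06 and 2.8e-07), with adjusted p = 0.225 each with an estimated correlation. They passed with fry (adjusted p = 0.00847, 0.00847 and 0.00990). Fry also called brassinosteroid (0.00847), cytokinin response (0.00957), gibberellin (0.00990), Aux/IAA (0.0105) and photosynthetic tissue (0.0321), which camera did not call. The replicate block ended every one of these fry calls (smallest adjusted p = 0.227), with fewer degrees of freedom left to the test. Camera with the block still called the first 3 lists down (adjusted p = 4.5e-28, 1.9e-09 and 7.9e-08).

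In the Aux/IAA list 6 members were lower at 30 min, including IAA3 (-0.81 ± 0.09), IAA1 (-0.74) and IAA2 (-0.73), and 2 were higher, IAA5 (0.92 ± 0.11) and IAA6 (0.50). Touch and rapid stress genes were split, with TCH3 (-1.32 ± 0.07), TCH4 (-0.72) and ERF104 (-0.45) lower and ZAT6 (0.72 ± 0.10), TCH2 (0.61) and ZAT12 (0.38) higher. The gibberellin list had RGL1, a repressor of gibberellin response (0.80 ± 0.10), and GASA6 (0.78) higher, and jasmonate and wounding had 3 members higher, VSP1 (0.81), VSP2 (0.44) and OPR3 (0.32), and 3 lower, JAZ9 (-0.55), LOX3 (-0.46) and JAZ3 (-0.34). PIN3 was lower by a log2 of -0.36 ± 0.08.

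**Figure D4:**
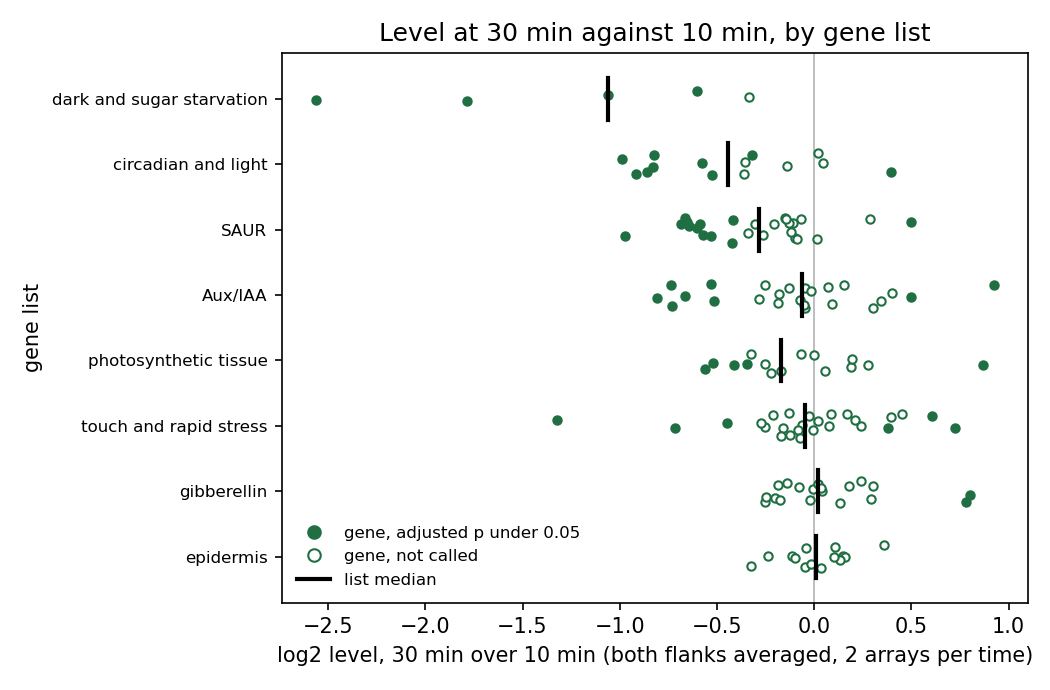
Log2 level at 30 over 10 min, averaged over both flanks (2 arrays per time), for each gene of 8 lists; filled points are genes with an adjusted p under 0.05 and black bars list medians. The dark and sugar starvation median is -1.06, the circadian and light median -0.44 and the epidermis median 0.00947.

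Camera did not call the other lists for this level. Their medians were -0.06 for Aux/IAA (adjusted p = 0.119), 0.11 for GH3 and other early auxin-induced genes (0.496), -0.02 for auxin transport and perception (0.862), -0.00603 for gravity sensing (0.753), 0.02 for gibberellin (0.713), -0.19 for brassinosteroid (0.496), -0.01 for ethylene (0.809) and -0.16 for cytokinin response (0.186). They were -0.10 for jasmonate and wounding (0.496), -0.04 for touch and rapid stress (0.778), 0.05 for expansins and xyloglucan enzymes (0.580) and for heat shock (0.862), -0.17 for photosynthetic tissue (0.120), 0.00947 for epidermis (0.862), -0.10 for xylem and fibre (0.713), -0.04 for phloem and cambium (0.949) and 0.08 for flower (0.778).

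In all, 1432 genes were called for the level, 608 higher and 824 lower at 30 min; of the 100 at or above 2-fold, 8 were higher and 92 lower. The share higher, 42.5%, was 27.6% with the deposited processed signals (691 calls). In the blocked fit it was 49.8% (2023 calls). Leaving out 10 min replicate 1 or 2 gave 709 (35.0% higher) or 1365 (44.8%) calls, 30 min replicate 1 gave 378 (19.8%), and 30 min replicate 2 gave 3811 (54.4%), where the larger side was the higher one. Time and plants cannot be told apart in this comparison, because each time rests on its own harvest and no unstimulated stem was measured.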

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

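The comparison of the 2 times was planned; the tests of explanations below were chosen only after the results were seen. Close SAUR neighbours, sought only among the genes of the SAUR list, were first defined within 3 genes. The window was widened to 10 after the result was seen, because it had left SAUR19 apart from its group on chromosome 5. Both results are given.

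The flank difference at 30 min differed from that at 10 min by the test of the difference for 23 genes. Of the named ones, IAA5 (2.17), AT5G66580 (1.74), AT5G02760 (1.203), HAT2 (1.18), AUF1 (0.97), IAA3 (0.98), IAA6 (0.90) and ARR7 (0.76) moved toward the lower flank. So did SAUR25 (1.196), SAUR19 (1.26), SAUR22 (1.23), SAUR24 (1.17), SAUR23 (1.16), SAUR21 (1.15), SAUR20 (1.12), SAUR66 (1.098) and SAUR63 (0.94). NIA1 (-0.69), AT1G79160 (-0.85), BT2 (-0.94) and AT1G78170 (-1.19) moved toward the upper flank.

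The same test by camera separated the times for 9 lists. The median change was 0.53 for SAUR, 0.11 for Aux/IAA, 0.18 for brassinosteroid and 0.0427 for ethylene. It was -0.18 for phloem and cambium, -0.13 for photosynthetic tissue, -0.11 for epidermis, -0.0898 for xylem and fibre secondary wall, and -0.0532 for expansins and xyloglucan enzymes. None held with an estimated correlation (smallest adjusted p = 0.348), and only SAUR passed with fry (adjusted p = 0.0236). In the blocked fit camera no longer called the last (adjusted p = 0.0714), and SAUR no longer passed with fry (adjusted p = 0.107).

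SAUR genes were higher in the lower flank already at 10 min, by camera at its preset correlation, when no single gene passed over all genes; the call was lost with an estimated correlation (adjusted p = 0.359) and with fry (0.0600, and 0.206 with the replicate block). Unequal shares of the epidermis and of xylem and fibres are argued against as the whole cause: their marker genes had medians of 0.00364 (SD 0.0505) and 0.0142 (SD 0.0389) at 10 min, against 0.21 for SAUR. Unequal shares of photosynthetic tissue (median -0.0157, SD 0.182) and of phloem and cambium (median 0.0689, SD 0.0650) cannot be told apart from regulation, the first because its genes spread widely and the second because camera called that list up as well (adjusted p = 0.0124; adjusted p = 0.544 with an estimated correlation). Signal shared between probes of tandem SAUR genes may account for part of the count of members. The 8 members with no other listed SAUR gene within 10 genes had a median of 0.0377 and an SD of 0.0512. Medians were 0.43 in the chromosome 5 group and 0.38 in the chromosome 1 group, where AT1G29490 had 0.01. They were 0.25 in the chromosome 4 group (3 genes) and 0.07 in the chromosome 2 group (2 genes). SAUR genes outside the list were not counted as neighbours, so the 8 may have some. Of these 8, 3 were above 0 on both 10 min arrays, and their median at 30 min was -0.0351. They went both ways at 30 min, with SAUR50 (0.55), SAUR10 (0.28) and SAUR76 (0.24) above 0. SAUR32 (-0.23), SAUR36 (-0.12), SAUR72 (-0.08), SAUR41 (-0.05) and SAUR8 (-0.02) were below 0. As a set at 10 min the 8 passed limma camera at its preset correlation (adjusted p = 0.0259). The set did not pass with an estimated correlation (adjusted p = 0.148) or with fry (adjusted p = 0.0975). It therefore does not exclude that sharing spread the difference of fewer genes to the probes of their neighbours. Sharing alone cannot make a flank ratio where no transcript differs between the flanks. With the first window of 3 genes there were 9 single members, SAUR19 (0.41) among them, with a median of 0.0397 and an SD of 0.130. That set passed limma camera (adjusted p = 9.2e-04) and fry (adjusted p = 0.0132) and did not pass with an estimated correlation (adjusted p = 0.0749), so the widened window made the case against sharing weaker. A biological difference among SAUR subfamilies stays open and was not tested.

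Many small flank differences appeared once the dye was in the fit. The flank contrast between times varied over genes 14.0 times as much as the contrast that belongs to neither flank, time nor dye. That is consistent with a single RNA per flank and time labelled with both dyes, in which case small differences between hand-cut flanks would be measured again on the swapped array. Unequal tissue shares in the cut flanks at 30 min are a candidate explanation that cannot be told apart from gene regulation here. The marker genes then had a median of -0.0903, with a standard error over genes of 0.0147. Genes of the same cut stems are not independent, so this is no error over arrays or plants. In size that median is close to the median of 0.0922 of the differences called with the dye term. At 10 min the same markers had a median of 0.0117 (standard error over genes 0.0197), with 16 above and 6 below 0 on both arrays. The 4224 differences called there had a median size of 0.0858, so the match in size is limited to 30 min. A true response of each gene to gravity, the difference that the design names, also stays open.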

How the results depend on the processing

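The alternatives were planned, except the arrays of each time averaged as 1 replicate and both alternatives for the comparison of replicates, which were chosen after seeing the data. With all arrays kept, 81 of 111 counts stayed within 1.5 times. In every setting all 96 genes called at 30 min kept their direction where they had a value. In part this was fixed in advance and is then no evidence of robustness. For genes measured on all arrays, the 30 min mean is the same with the replicate block, another variance model, or each time fitted alone. It is also the same with an array of the other time left out. The mean over all probes changes only genes with several probes. Direction could change with another background correction, the deposited signals or series table, median centring, or a 30 min array left out. Values changed as follows; the cause was not tested unless given.

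The replicate block called 4224 genes at 10 min, 6259 at 30 min, 3629 for the mean and 6879 for the difference, and 3 lists at 10 min; it changed no other count by over 1.5 times. A normexp offset of 16 called 47 genes at 30 min (42 and 5) and put 1 gene 1.5-fold apart on both 10 min arrays. The deposited processed signals called 60 genes at 30 min (50 and 10), 2 for the difference, 691 for the level (191 and 500) and 3 lists at 10 min, with 4 and 83 genes 1.5-fold apart on both arrays at 10 and 30 min. The series table, with the same ratios, called 61 (50 and 11), 2 and 3, with 4 and 83. Median centring in place of loess called 0 genes at 30 min, 0 for the mean and 0 for the difference, while 35 genes were 1.5-fold apart on both 30 min arrays. Each time fitted alone called 86 genes at 10 min (64 and 22) and 613 at 30 min (228 and 385, so that the larger side was the upper flank); it gives no value for the mean or the difference. The estimated correlation called 0 lists at 10 min, 0 at 30 min and 0 for the mean, and fry 0 at 10 min and 7 for the mean. At 2-fold, 20 genes were apart on both 30 min arrays. The arrays of each time averaged as 1 replicate called 0 genes for the mean.

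Leaving out each array in turn called 44 to 104 genes at 10 min, 214 to 613 at 30 min, 134 to 212 for the mean, 237 to 430 for the difference, 378 to 3811 for the level, and 3 to 5 lists at 10 min. The lone array of a time is then assumed to vary like the other time and its dye is not balanced. For the flank difference of that other time, leaving out either array repeats its fit alone, so these settings are not separate checks. All 96 genes remained called in 3 of the 4 settings and 93 without 30 min replicate 2.

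Of 5093 values of named genes under alternatives, 4190 kept direction and side of the threshold, 350 lost the call, 547 gained it and 0 turned over with a call. Where a setting left the values unchanged, only the call could change. The 6 of opposite sign, called under neither fit, arose with an array left out, and over the arrays left out the values were -0.0679 to 0.174 for IAA2 at 10 min, -0.0324 to 0.0428 for PIN3 at 10 min, and for GH3.3 -0.0459 to 0.0634 (difference; also -0.0439) and -0.114 to 0.0983 (level; also 0.0656). The SD ratio of arrays of one time over arrays of different times was 0.512, and 0.519 with processed signals. Signal over background limits dim genes: in the filter requiring both channels on all arrays 104 genes were called at 30 min, and without a filter 74. With any array left out the larger side at 30 min was the upper flank and for the difference the downward one; for the level it turned only without 30 min replicate 2. A slide block was not run, since each slide held 1 array.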

Other observations

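The tests in this part were chosen only after the results were seen. Each flank's own level was compared between the times, with both channels scaled as for the level. Among the 60 genes higher in the lower flank at 30 min, the median change from 10 to 30 min was -0.56 in the upper and 0.18 in the lower flank. IAA1, the auxin-induced repressor, had -1.33 in the upper and -0.15 in the lower flank, IAA3 -1.299 and -0.32, SAUR66 -1.08 and 0.02, and ARR7 -1.17 and -0.42. IAA5 went the other way, with 2.01 in the lower and -0.16 in the upper flank, as did IAA6 (0.95 and 0.05). The SAUR list had a median of -0.72 in the upper flank, with 16 of 26 members called lower, and -0.02 in the lower flank, with 6 called higher and 5 lower.

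Among the 36 genes higher in the upper flank at 30 min, 22 were called lower in the lower flank at 30 than at 10 min (median -0.48). In the upper flank 12 were called higher and 10 lower. AT1G78170 had 1.16 in the upper and -0.03 in the lower flank, while BT2, a gene of the BTB and TAZ domain family, had -2.51 and -3.44.

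A hypothesis was that the flank difference at 30 min came from a rise in the lower flank between the times rather than a fall in the upper flank. Of the 60 genes, 38 were called lower in the upper flank at 30 than at 10 min and 24 were called higher in the lower flank. Over all genes, 526 were called higher and 649 lower in the upper flank, against 1309 and 1360 in the lower flank. Calls were thus more frequent in the lower flank, and the counts of the 60 genes are not on an equal footing. They do not decide between a rise and a fall. Plants harvested at 30 min may have had lower levels of these genes in both flanks before the stimulus. A rise in the lower flank alone would then give such counts. A lower start cannot be told apart from a response in the upper flank, whose median change was -0.56, because no unstimulated stem was measured. Scaling of whole arrays was not settled either: with quantile scaling of all channels the median was -0.55, but that setting hardly moved any median and any scaling of whole arrays holds the median of all genes near 0.

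The clock genes CCA1 and LHY, which act together, had 0.35 and 0.27 at 10 min and 0.14 and 0.34 at 30 min. RVE2, a related gene named after its values were seen, had 0.31 at 10 min and -0.00672 at 30 min. Of 38 genes with several probes well above background on all arrays, 0 had probes more than 0.3 apart in log2 ratio at 30 min. As 0 of the 38 were called at 30 min, this says nothing of the agreement of probes for called genes. Of 818 probes that named no or several loci and were well above background, 0 were at least 1.5-fold apart in the same direction on both 30 min arrays.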
